A study of Homo sapiens with 91 samples.

How the data were processed

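The study measured RNA in MOLT4, PSN1 and RH4 cells treated with KI-CDK9d-32, KB-0742 or DMSO. Cells were lysed, the same amount of a Lexogen mix of ERCC and SIRV spike-in RNA was added to each thawed lysate, and RNA was extracted on beads. Libraries came from 1 ng of total RNA by a reduced-volume SMART-seq2 protocol with Nextera XT, without strand information or molecular identifiers. Per the labels, the submitters' processing notes name Salmon and the hg38 build, and the Salmon version and annotation release are not given. The deposited tables hold, for each line, the expected counts per gene, which are Salmon estimates rounded to whole numbers, and log2 values of TPM plus 1. The log2 unit was tested on the values, where the powers of 2 less 1 sum to the same total in every library, spike-ins included. Each table has 62856 entries, with 62757 genes, 92 ERCC and 7 SIRV spike-ins, and every column was matched to 1 sample. 47 entries for the pseudoautosomal regions of the Y chromosome were left out. Gene names came from the reference tables used here, and positions and lengths from GENCODE release 29 (GRCh38), matched by identifier without version.

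Samples were grouped by line, compound and time from the labels, and 28 comparisons were made, namely each compound with vehicle and with the other compound at the same time, and the change of each compound effect from 4 h to 8 h. Counts were analyzed in R 4.3.3 with edgeR 4.0.16, 1 fit per line with all its groups. Genes were kept by filterByExpr with a minimum count of 10, which left 11664 genes in MOLT4, 12471 in PSN1 and 12058 in RH4 and set aside 0.437%, 0.584% and 0.683% of gene counts. Scaling used TMM, and tests were robust quasi-likelihood F tests with Benjamini-Hochberg adjustment within each comparison at 0.05. The standard error of a log2 fold change is its size divided by the root of F. The biological coefficient of variation was 0.21, 0.252 and 0.217 in MOLT4, PSN1 and RH4. Replicate libraries varied at least 3.218, 3.578 and 3.383 times as much as counting alone gives (chi-square per degree of freedom), so counting intervals understate their spread.

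Because CDK9 acts in transcription, the total RNA of treated cells may not be assumed equal to that of vehicle, and TMM values are relative to the other genes of the same libraries. Spike-in scaling, with library sizes set by the summed spike-in counts, was therefore run for every comparison, and its values are given where direction or balance differs. Spike-in shares were compared by two-sided exact permutation tests over all arrangements of the libraries of 2 groups (70 for 4 against 4), adjusted over 22 comparisons. An equal spike-in amount per lysate measures RNA per lysate, and cell numbers at lysis were not measured in the data used here.

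26 gene lists (887 genes) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They were MYC targets, the MYC-MAX network, immediate-early genes, P-TEFb and elongation factors, other transcription-linked CDKs, RNA polymerase II subunits, anti-apoptotic genes, pro-apoptotic genes, replication-dependent histones, p53 targets, G2/M genes, DNA replication and E2F targets, and DNA repair genes. The others were the integrated stress response, heat shock, interferon-stimulated genes, splicing factors, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation genes, nuclear long noncoding RNAs, snoRNA-host noncoding RNAs, reference genes, and markers of T-lineage leukemia, of epithelial and pancreatic carcinoma, and of myogenic and fusion-positive rhabdomyosarcoma. Lists and members came from general knowledge, as no outside gene sets were used. Not every list is described at every time, and the comparisons described were chosen after its values were seen. As a check of sample identity, the marker list of a library's own line was the highest of the 3 marker lists in 35 of 35, 32 of 32 and 24 of 24 libraries.

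The named-genes rule, the lists, the tests, the filter and the alternatives were fixed before the data were examined. Named genes are 7 fixed genes (CDK9, CCNT1, HEXIM1, MYC, MYCN, MCL1 and POLR2A), and up to 5 genes with the highest and up to 5 with the lowest fold change per comparison at 4 h and 8 h among called genes with a mean log2 CPM of at least 3 and no overlap between groups. For each list they are the 3 called members with the largest change with KI-CDK9d-32 at 8 h or in the comparison described. At 2 h in MOLT4, DDIT3 and DDIT4 are named as the 2 lowest of such genes, a choice made after their values were seen. Some genes that the rule names are not reported here. Genes without a symbol were left out, and so were list members named by the rule whose call was lost when 1 library was left out. That last omission was chosen after the values were seen, and calls of that kind that remain are given with the libraries they rest on.

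The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma with a trend on the deposited log2 TPM, no filter on low counts, only the libraries of the groups compared, spike-in scaling, ERCC or SIRV spike-ins alone for the shares, a replicate block, each library left out in turn, and a threshold of 1 on the absolute log2 fold change for shared calls. A further setting without the 6 libraries of replicate 3 at 4 h and 8 h in MOLT4, and a test of spike-in shares between libraries of the same number, were chosen after seeing the data. The count test was tested on simulated data with the dispersions of each line, for KI-CDK9d-32 against vehicle at 8 h. With 200 genes changed in each line, it called 134 of 11664 genes in MOLT4, 125 of 12471 in PSN1 and 145 of 12058 in RH4, and 5, 8 and 9 of these calls were unchanged genes.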

Results

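RNA was sequenced from 91 libraries of human cell lines treated with KI-CDK9d-32, a degrader of the kinase CDK9, with KB-0742, a CDK9 inhibitor, or with DMSO vehicle. The lines were MOLT4 (acute lymphoblastic leukemia, 35 libraries), PSN1 (pancreatic adenocarcinoma, 32) and RH4 (rhabdomyosarcoma, 24). Cells were collected at 2, 4 and 8 h in MOLT4 and PSN1 and at 4 and 8 h in RH4, and PSN1 had no KB-0742 group at 2 h. Each of the 23 groups held 4 libraries except MOLT4 vehicle at 4 h, which held 3. The study's design text writes RH1 where every sample label says RH4, and the labels give no doses. Gene counts summed to between 1598283 and 3240753 per library in MOLT4, 1998712 and 3227113 in PSN1, and 1670111 and 3136769 in RH4. The tests covered 11664, 12471 and 12058 genes.

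Changes below are log2 fold changes ± standard error, relative to the other genes of the same libraries, from the edgeR quasi-likelihood test with TMM scaling and Benjamini-Hochberg adjustment at 0.05. Groups have n = 4 unless stated, and levels are CPM ± SD. A group with no counts gives a bound against a floor of 3 counts over the group, and a group with 1 to 3 counts gives a ratio of counts with its 95% counting interval. Such intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The labels call the replicates biological but do not mention separate cultures, so p-values measure the spread between these samples. Libraries were unstranded, so antisense or overlapping partners such as RPL30-AS1, MPRIP-AS1 and TUBA1B-AS1 could not be told apart from their neighbors. Values of pseudogenes and near-identical copies, among them PSMC1P1, PI4KAP1, RPL21P28, SNORD3B-1 and the histone and ribosomal protein genes, are uncertain.

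7 genes of the CDK9 pathway and the MYC network were fixed in advance and located in GRCh38, GENCODE release 29. CDK9 (ENSG00000136807) lies on chromosome 9 at 127785679 to 127790787 and encodes the kinase that both compounds target. CCNT1 (ENSG00000129315), on chromosome 12 at 48688458 to 48716998, encodes its partner cyclin T1 in the elongation factor P-TEFb. HEXIM1 (ENSG00000186834), on chromosome 17 at 45148502 to 45152101, encodes an inhibitor of P-TEFb. MYC (ENSG00000136997), on chromosome 8 at 127735434 to 127741434, and MYCN (ENSG00000134323), on chromosome 2 at 15940564 to 15947007, encode transcription factors. MCL1 (ENSG00000143384), on chromosome 1 at 150574551 to 150579738, encodes a short-lived survival protein. POLR2A (ENSG00000181222), on chromosome 17 at 7484366 to 7514616, encodes the largest subunit of RNA polymerase II.

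An equal amount of spike-in RNA was added to each lysate, so its share of the reads rises where the cells yield less RNA. In MOLT4 at 8 h the spike-in share was 14.5% ± 1.91 with vehicle, 21.5% ± 2.59 with KB-0742 and 39.9% ± 14.8 with KI-CDK9d-32 (SD, n = 4 each). In PSN1 at 8 h it was 12.6% ± 0.462 with vehicle, 17.3% ± 2.28 with KI-CDK9d-32 and 17.1% ± 3.58 with KB-0742. In these 4 comparisons with vehicle, 4 of 4 treated libraries lay above all vehicle libraries, as did 4 of 4 MOLT4 KI-CDK9d-32 libraries above all KB-0742 libraries. Each of the 5 reached the smallest p its 70 arrangements allow (two-sided exact permutation p = 0.0286). In RH4 at 8 h the share was 9.71% ± 2.07, 12.9% ± 2.03 with KI-CDK9d-32 and 15.1% ± 2.22 with KB-0742, with 3 of 4 treated libraries above all vehicle libraries for each compound (exact p = 0.0571). None of the 22 comparisons passed correction, with a smallest Benjamini-Hochberg adjusted p of 0.126.

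**Figure D1:**
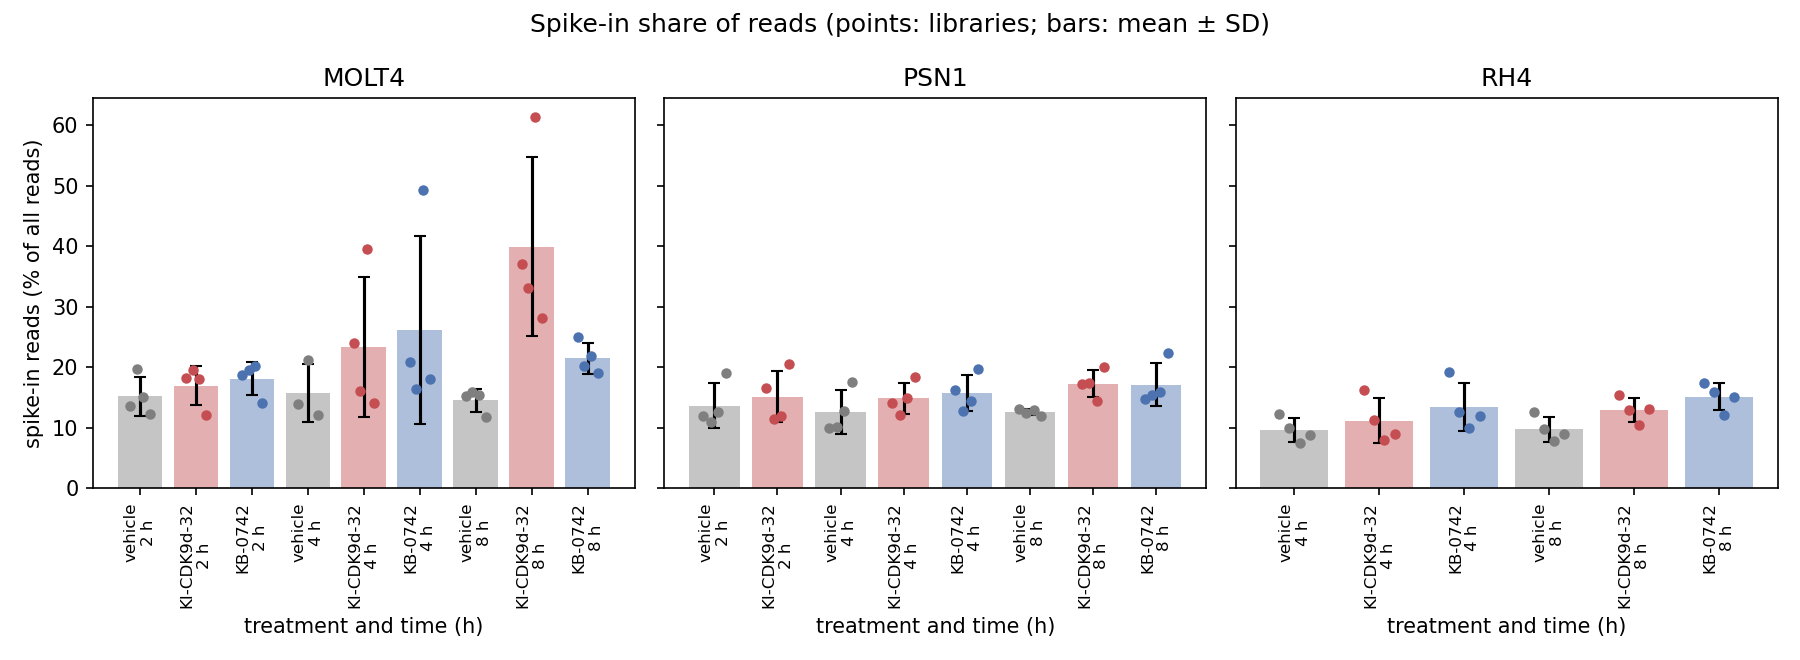
Spike-in reads as a percentage of all reads in each library (points), with the mean and SD of each group (bars), for the 3 lines by time and treatment. At 8 h the 4 MOLT4 libraries treated with KI-CDK9d-32 averaged 39.9% against 14.5% with vehicle.

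The first question was what the degrader does to MOLT4 transcripts, the MYC network in the study's title among them. MYC fell at 2, 4 and 8 h (-1.99 ± 0.15, -2.77 ± 0.17 and -1.91 ± 0.16), from 156 ± 27.6 CPM (n = 3) to 22.2 ± 7.76 CPM at 4 h. At 2 h the immediate-early list members DUSP1 (-4.65 ± 0.75) and GADD45B (count ratio 0.0736, 0.0146 to 0.229) fell, and DDIT3 (-3.50 ± 0.36) and DDIT4 (-3.19 ± 0.27) were the lowest under the naming rule. DUSP1 encodes a MAP kinase phosphatase, DDIT3 a stress-induced transcription factor, and DDIT4 an inhibitor of mTOR signaling. Of 27 immediate-early genes at 2 h, 16 were lower and 11 not called (18 lower adjusted over the list alone). Immediate-early genes had a median of -1.81 and -1.72 with members at 0 at their bounds (camera adjusted p = 1.11e-16). By 8 h this had turned for several members, with FOS (5.81 ± 0.99), ID2 (4.96 ± 0.58) and EGR1 (4.46 ± 0.73) above vehicle. The list was not called then (8 higher, 5 lower and 14 not called of 27, 8 higher and 5 lower adjusted over the list alone, median 0.09, -2.75 with spike-in scaling, camera adjusted p = 0.443).

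Genes called with KI-CDK9d-32 against vehicle in MOLT4 numbered 1164 at 2 h (533 higher, 631 lower), 3797 at 4 h (1591, 2206) and 5781 at 8 h (2428, 3353). With spike-in scaling the median gene shifted by -0.41, -1.13 and -2.99, and the calls became 20 higher and 193 lower, 80 higher and 4310 lower, and 100 higher and 10609 lower. The highest changes at 4 h were HELLPAR (2.56 ± 0.27), 7SK (2.08 ± 0.29) and TNFRSF13C (2.01 ± 0.34). HELLPAR is a long noncoding RNA, 7SK the small nuclear RNA that holds P-TEFb inactive, and TNFRSF13C the receptor for the cytokine BAFF. The lowest were SCO2 (-4.96 ± 0.42), PET117 (-4.35 ± 0.46), GIMAP5 (-4.27 ± 0.58), RP9 (-3.84 ± 0.35) and RPUSD2 (-3.80 ± 0.38). SCO2 and PET117 serve assembly of cytochrome c oxidase. At 8 h the highest were 7SK (4.51 ± 0.25), LINC01550 (3.46 ± 0.27) and TUBA1B-AS1 (3.09 ± 0.47), and the lowest were PSMC1P1 (at least 36.3-fold lower), PI4KAP1 (count ratio 0.0134, 0.00162 to 0.0489), MSANTD7 (count ratio 0.0222, 0.00266 to 0.0811), PET117 (-5.27 ± 0.52) and PDCD2L (count ratio 0.0252, 0.00516 to 0.0744). MCL1 fell at 4 h (-0.97 ± 0.35), a call lost without any 1 of 5 libraries (highest adjusted p = 0.0786, without MOLT4 vehicle 4 h replicate 3). POLR2A fell at 2 h (-0.50 ± 0.14) and 4 h (-0.40 ± 0.16). Its 2 h call was lost without any 1 of 2 libraries (highest adjusted p = 0.0638, without MOLT4 KI-CDK9d-32 2 h replicate 1), and its 4 h call without any 1 of 4 libraries (highest adjusted p = 0.165, without MOLT4 KI-CDK9d-32 4 h replicate 4). CCNT1 rose at 8 h (0.85 ± 0.26), or -1.95 with spike-in scaling, the opposite direction.

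Of 63 MYC targets at 8 h, 6 were higher, 41 lower and 16 not called (6 higher and 42 lower adjusted over the list alone). MYC targets had a median of -1.0 (camera adjusted p = 2.48e-08). The largest falls were in GRWD1 (-3.62 ± 0.22), NOP16 (-2.71 ± 0.17) and NDUFAF4 (-2.53 ± 0.29), the first 2 of them ribosome assembly factors. Of 10 MYC-MAX network genes at 4 h, 5 were lower and 5 not called (5 lower adjusted over the list alone). MYC-MAX network genes had a median of -0.74 (camera adjusted p = 0.00203). MGA and MLXIP, dimer partners in that network, fell at 4 h (-1.22 ± 0.25 and -0.77 ± 0.21), and MAX and MLX fell at 8 h (-1.38 ± 0.14 and -1.24 ± 0.16). Of 22 integrated stress response genes at 4 h, 2 were higher, 11 lower and 9 not called (2 higher and 12 lower adjusted over the list alone). Integrated stress response genes had a median of -0.82 (camera adjusted p = 2.35e-04). SESN2 led these (at least 18.4-fold lower), followed by TRIB3 (count ratio 0.0474, 0.00956 to 0.144) and PPP1R15A (-3.38 ± 0.58). Of 51 replication-dependent histones at 8 h, 38 were higher and 13 not called (40 higher adjusted over the list alone). Replication-dependent histones had a median of 1.56 (-1.22 with spike-in scaling, camera adjusted p = 7.05e-09). H4C12 (at least 40.8-fold higher), H2AC6 (4.07 ± 0.48) and H4C2 (3.76 ± 0.82) rose the most, though H4C12 was not called without MOLT4 KI-CDK9d-32 8 h replicate 2 (adjusted p = 0.0863). Of 14 pro-apoptotic genes at 8 h, 7 were lower and 7 not called (7 lower adjusted over the list alone). Pro-apoptotic genes had a median of -1.06 (camera adjusted p = 0.117). Among these, TNFRSF10B (at least 4.5-fold lower), BIK (-2.69 ± 0.73) and BAK1 (-2.62 ± 0.21) fell, while CDKN1A, the p21 cell-cycle inhibitor, rose (4.36 ± 0.76). Of 19 heat shock genes at 8 h, 4 were higher, 9 lower and 6 not called (4 higher and 9 lower adjusted over the list alone). Heat shock genes had a median of -0.83 (camera adjusted p = 0.0086, adjusted p = 0.253 with an estimated correlation). The chaperone genes DNAJA1 and HSPA8 fell (-2.85 ± 0.13 and -2.69 ± 0.12) and HSPB1 rose (2.17 ± 0.29, or -0.50 with spike-in scaling, the opposite direction). Of 13 mitochondrially encoded mRNAs at 8 h, 13 were higher (13 higher adjusted over the list alone). Mitochondrially encoded mRNAs had a median of 2.14 (-0.68 with spike-in scaling, camera adjusted p = 4.87e-45). Of 79 ribosomal protein mRNAs at 8 h, 79 were higher (79 higher adjusted over the list alone). Ribosomal protein mRNAs had a median of 1.39 (-1.44 with spike-in scaling, camera adjusted p = 7.28e-130). Of 18 reference genes at 8 h, 13 were higher, 4 lower and 1 not called (13 higher and 4 lower adjusted over the list alone). Reference genes had a median of 0.67 (-2.10 with spike-in scaling, camera adjusted p = 1.12e-09).

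KB-0742 was set against vehicle in MOLT4 to ask how blocking the kinase compares with removing it. HEXIM1 fell at 2, 4 and 8 h (-2.51 ± 0.40, -2.80 ± 0.46 and -2.00 ± 0.37), from 18.2 ± 4.79 CPM to 4.42 ± 2.19 CPM at 8 h. CCNT1 rose over the same times (0.75 ± 0.24, 1.44 ± 0.26 and 1.95 ± 0.24), and its paralog CCNT2 rose at 8 h (2.73 ± 0.29). MYC rose at 2 h (0.91 ± 0.14) and 4 h (1.02 ± 0.15) and was not called at 8 h, at 165 ± 31.5 CPM against 169 ± 9.97 with vehicle. CDK9 rose at 8 h (1.16 ± 0.30), and POLR2A fell at 4 h (-0.42 ± 0.16) and 8 h (-0.98 ± 0.15). The 4 h call of POLR2A was lost without any 1 of 5 libraries (highest adjusted p = 0.13, without MOLT4 vehicle 4 h replicate 3), and the 2 h call of CCNT1 without any 1 of 2 libraries (highest adjusted p = 0.0755, without MOLT4 KB-0742 2 h replicate 2). With spike-in scaling CCNT1 at 2 h (-0.06), MYC at 4 h (-0.28) and CDK9 at 8 h (-0.17) took the opposite direction, and MYC at 2 h was 0.10 and CCNT1 0.09 at 4 h and 0.59 at 8 h.

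Called genes numbered 3040 at 2 h (1535 higher, 1505 lower), 4174 at 4 h (2108, 2066) and 5739 at 8 h (2730, 3009). Spike-in scaling shifted the median gene by -0.86, -1.38 and -1.41 and gave 14 higher and 2282 lower, 52 higher and 5893 lower, and 71 higher and 6332 lower. Among the highest changes at 4 h were RPL21P28 (3.68 ± 0.50), HELLPAR (2.94 ± 0.27) and RPL30-AS1 (2.89 ± 0.38), and the lowest were UNC50 (-3.97 ± 0.43), C14orf119 (-3.47 ± 0.29), MRPL46 (-3.40 ± 0.32), BIN3 (-3.35 ± 0.37) and RFC4 (-3.26 ± 0.22). RFC4 encodes a subunit of the clamp loader of DNA replication. Among the highest at 8 h were HELLPAR (4.32 ± 0.25), DNHD1 (3.29 ± 0.33) and CCNL1 (2.92 ± 0.17). CCNL1 encodes cyclin L1, a partner of the CDK11 kinases. The lowest at 8 h were UPK3BL1 (at least 64.3-fold lower), SLC25A4 (-4.17 ± 0.25), OGG1 (-4.13 ± 0.51), LINC02273 (-3.96 ± 0.50) and WDR73 (-3.49 ± 0.36). SLC25A4 encodes the mitochondrial ADP/ATP carrier, and OGG1 the glycosylase that removes 8-oxoguanine from DNA.

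Of 48 splicing factor genes at 8 h, 33 were higher, 5 lower and 10 not called (33 higher and 5 lower adjusted over the list alone). Splicing factor genes had a median of 0.79 (-0.53 with spike-in scaling, camera adjusted p = 2.93e-13). PRPF3 (2.63 ± 0.15), RBM39 (2.04 ± 0.10) and U2AF2 (1.91 ± 0.18) rose the most. Of 16 snoRNA-host noncoding RNAs at 8 h, 13 were higher and 3 not called (13 higher adjusted over the list alone). SnoRNA-host noncoding RNAs had a median of 0.72 (-0.61 with spike-in scaling, camera adjusted p = 1.02e-08). The largest rises were in SNHG17 (1.65 ± 0.15), SNHG15 (1.24 ± 0.13) and SNHG16 (1.15 ± 0.12), of which SNHG15 (-0.11) and SNHG16 (-0.18) took the opposite direction with spike-in scaling. Of 13 genes of other transcription-linked CDKs and cyclins at 8 h, 8 were higher, 2 lower and 3 not called (8 higher and 2 lower adjusted over the list alone). Genes of other transcription-linked CDKs and cyclins had a median of 0.74 (-0.54 with spike-in scaling, camera adjusted p = 0.0161, adjusted p = 0.0664 with an estimated correlation). Of 22 P-TEFb and elongation factor genes at 8 h, 12 were higher, 8 lower and 2 not called (12 higher and 8 lower adjusted over the list alone). P-TEFb and elongation factor genes had a median of 0.80 (-0.49 with spike-in scaling, camera adjusted p = 0.099). Of 45 replication and E2F target genes at 8 h, 5 were higher, 23 lower and 17 not called (5 higher and 23 lower adjusted over the list alone). Replication and E2F target genes had a median of -0.41 (camera adjusted p = 0.00133, adjusted p = 0.236 with an estimated correlation). POLA2, RFC4 and CDC45 fell the most (-2.49 ± 0.25, -2.40 ± 0.19 and -2.05 ± 0.17). Of 38 G2/M genes at 8 h, 24 were higher, 4 lower and 10 not called (24 higher and 4 lower adjusted over the list alone). G2/M genes had a median of 0.71 (-0.62 with spike-in scaling, camera adjusted p = 5.9e-05, adjusted p = 0.162 with an estimated correlation). KIF23 (1.90 ± 0.27), ANLN (1.60 ± 0.24) and CCNA2 (1.59 ± 0.12) led the rises. Of 32 interferon-stimulated genes at 8 h, 3 were higher, 16 lower and 13 not called (3 higher and 17 lower adjusted over the list alone). Interferon-stimulated genes had a median of -0.83 (camera adjusted p = 0.0245, adjusted p = 0.167 with an estimated correlation). Of 43 nuclear oxidative phosphorylation genes at 4 h, 37 were higher, 2 lower and 4 not called (38 higher and 2 lower adjusted over the list alone). Nuclear oxidative phosphorylation genes had a median of 0.68 (-0.60 with spike-in scaling, camera adjusted p = 4.28e-18). Of 79 cytosolic ribosomal protein mRNAs at 8 h, 79 were higher (79 higher adjusted over the list alone). Cytosolic ribosomal protein mRNAs had a median of 1.06 (-0.27 with spike-in scaling, camera adjusted p = 1.66e-95).

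The degrader and the inhibitor were then compared directly in MOLT4 at matched times. MYC was lower with KI-CDK9d-32 at 2, 4 and 8 h (-2.89 ± 0.15, -3.78 ± 0.17 and -1.87 ± 0.16). HEXIM1 was higher (2.21 ± 0.41, 2.45 ± 0.46 and 2.37 ± 0.38), at 23.9 ± 12.2 CPM against 4.42 ± 2.19 with KB-0742 at 8 h, where spike-in scaling gave 0.67. At 8 h FOS, ID2 and FOSB were higher with the degrader (count ratio 166, 29.1 to 6610, 4.85 ± 0.60 and count ratio 27.1, 8.8 to 136), and the T-lineage transcription factor gene MYB was lower (-3.42 ± 0.20).

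Genes differing between the compounds numbered 2138 at 2 h (957 higher with KI-CDK9d-32, 1181 lower), 4164 at 4 h (1707, 2457) and 6823 at 8 h (3374, 3449). The spike-in shift of the median was 0.40, 0.28 and -1.46, and spike-in scaling gave 396 higher and 89 lower, 895 higher and 744 lower, and 274 higher and 6390 lower. The highest changes at 4 h were TRIM66 (3.94 ± 0.39), CCDC18-AS1 (3.46 ± 0.46) and TNFRSF13C (3.24 ± 0.39), and the lowest were PET117 (-5.47 ± 0.42), TOGARAM1 (-5.30 ± 0.42), ADPGK-AS1 (-5.21 ± 0.38), GIMAP5 (-4.80 ± 0.56) and SLC2A1 (-4.50 ± 0.43). SLC2A1 encodes the glucose transporter GLUT1. At 8 h the highest were LINC01550 (5.04 ± 0.33), TSPOAP1 (4.47 ± 0.31), PABPC1L (4.01 ± 0.40), CCS (3.98 ± 0.40) and PTK2B (3.90 ± 0.40), and the lowest were PSMC1P1 (at least 50.6-fold lower), MSANTD7 (count ratio 0.0118, 0.00142 to 0.043), PET117 (-6.13 ± 0.49), PI4KAP1 (count ratio 0.0169, 0.00203 to 0.0621) and SBDS (-5.50 ± 0.42). PTK2B encodes a focal adhesion kinase and SBDS a ribosome maturation factor.

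Of 63 targets of MYC at 8 h, 10 were higher, 44 lower and 9 not called (10 higher and 46 lower adjusted over the list alone). Targets of MYC had a median of -1.05 (camera adjusted p = 1.52e-13). GRWD1 (-4.87 ± 0.21) and WDR43 (-4.38 ± 0.22) differed most. Of 48 splicing factors at 8 h, 10 were higher, 27 lower and 11 not called (10 higher and 28 lower adjusted over the list alone). Splicing factors had a median of -0.73 (camera adjusted p = 1.49e-09). SRSF3, CLK4 and PRPF3 led them (-4.55 ± 0.11, -4.37 ± 0.49 and -3.51 ± 0.17). Of 16 snoRNA-host RNAs at 4 h, 15 were lower and 1 not called (15 lower adjusted over the list alone). SnoRNA-host RNAs had a median of -0.94 (camera adjusted p = 1.16e-16). Of 26 T-lineage leukemia markers at 8 h, 15 were higher, 1 lower and 10 not called (15 higher and 1 lower adjusted over the list alone). T-lineage leukemia markers had a median of 0.62 (-0.88 with spike-in scaling, camera adjusted p = 0.00319). ZAP70, which encodes a kinase of T-cell receptor signaling, was higher (2.09 ± 0.12). Of 51 histone genes at 8 h, 39 were higher and 12 not called (40 higher adjusted over the list alone). Histone genes had a median of 1.73 (camera adjusted p = 1.18e-07). Of 38 mitotic genes of the G2/M list at 8 h, 5 were higher, 26 lower and 7 not called (5 higher and 27 lower adjusted over the list alone). Mitotic genes of the G2/M list had a median of -0.94 (camera adjusted p = 1.85e-06, adjusted p = 0.0961 with an estimated correlation).

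**Figure D2:**
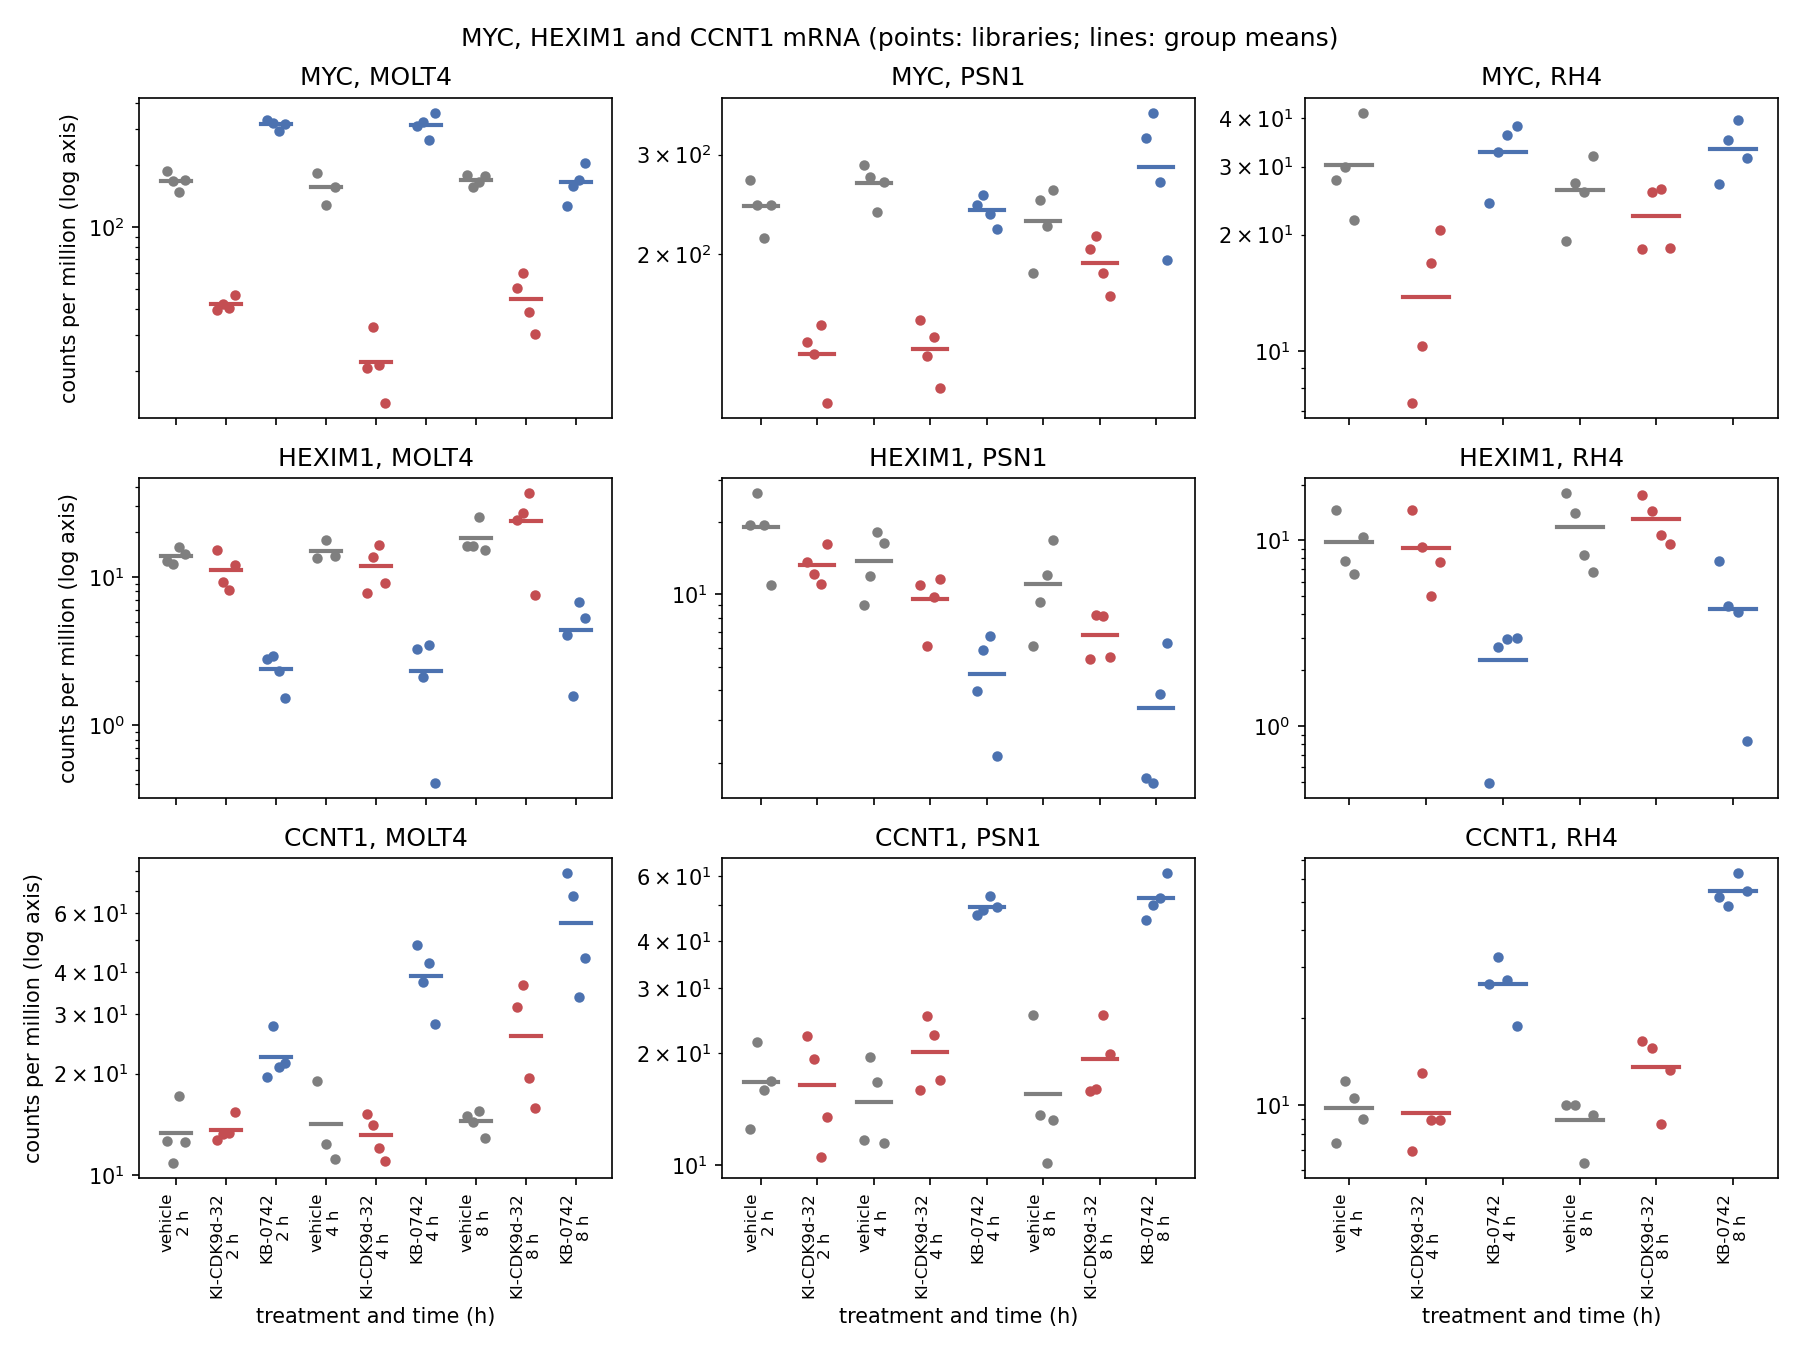
MYC, HEXIM1 and CCNT1 in CPM (log axis) in each library (points) with the group mean (line), for vehicle, KI-CDK9d-32 and KB-0742 by time in the 3 lines. In MOLT4 at 8 h MYC averaged 44.9 ± 12.9 CPM with KI-CDK9d-32 and 169 ± 9.97 CPM with vehicle.

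The degrader was next set against vehicle in PSN1, a pancreatic carcinoma line. MYC fell at 2 h and 4 h (-0.87 ± 0.14 and -0.97 ± 0.14), to 136 ± 15.9 CPM from 267 ± 21.8 at 4 h, and was not called at 8 h (193 ± 20.4 against 229 ± 33.2 CPM). With spike-in scaling MYC was -1.13, -1.58 and -1.21 at 2, 4 and 8 h. POLR2A fell at all 3 times (-0.97 ± 0.19, -1.07 ± 0.19 and -1.19 ± 0.20), and MCL1 rose at 8 h (0.60 ± 0.20), or -0.35 with spike-in scaling, the opposite direction. This call was lost without any 1 of 3 libraries (highest adjusted p = 0.123, without PSN1 KI-CDK9d-32 8 h replicate 3). At 2 h the stress-response genes DDIT3 (-1.29 ± 0.23), DDIT4 (-1.54 ± 0.34) and GADD45B (-1.73 ± 0.38) had fallen. DDIT4 was not called without any 1 of 5 libraries (highest adjusted p = 0.129, without PSN1 KI-CDK9d-32 2 h replicate 1), nor GADD45B without any 1 of 5 libraries (highest adjusted p = 0.101, without PSN1 KI-CDK9d-32 2 h replicate 4).

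Called genes numbered 60 at 2 h (16 higher, 44 lower), 918 at 4 h (452, 466) and 2576 at 8 h (1378, 1198). The 2 h count was 34 without PSN1 vehicle 2 h replicate 3, 34 without PSN1 vehicle 2 h replicate 4 and 37 without PSN1 KI-CDK9d-32 2 h replicate 3, and the 4 h count was 532 without PSN1 KI-CDK9d-32 4 h replicate 3 and 604 without PSN1 KI-CDK9d-32 4 h replicate 4. Spike-in scaling shifted the median gene by -0.29, -0.60 and -1.01 and gave 2 higher and 13 lower, 92 higher and 1553 lower, and 139 higher and 6382 lower. At 4 h the highest changes were LHFPL4 (4.48 ± 0.39), HELLPAR (3.09 ± 0.28), LINC00862 (2.70 ± 0.41) and ZNF30 (2.45 ± 0.22), and the lowest were RGS16 (-3.12 ± 0.35), DUSP2 (-2.53 ± 0.56), NOTCH2NLR (-2.51 ± 0.55), ALDH1A3-AS1 (-2.00 ± 0.32) and RGS2 (-1.99 ± 0.22). LHFPL4 encodes a membrane protein of inhibitory synapses, RGS16 and RGS2 regulators of G-protein signaling, and DUSP2 a phosphatase. The highest at 8 h were SNORD3A (count ratio 229, 78 to 1120), LHFPL4 (5.73 ± 0.44) and RPPH1 (3.66 ± 0.48), and the lowest were KIZ (-2.42 ± 0.38), TBX15 (-2.19 ± 0.37), ARMC5 (-2.14 ± 0.51), POLR3B (-2.12 ± 0.32) and ATXN7L2 (-2.11 ± 0.33). SNORD3A is the U3 small nucleolar RNA and RPPH1 the RNA of RNase P.

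Of 42 genes of the immediate-early list at 2 h, 4 were lower and 38 not called (11 lower adjusted over the list alone). Genes of the immediate-early list had a median of -0.55 (camera adjusted p = 3.5e-10). Of 23 stress response genes at 4 h, 6 were lower and 17 not called (1 higher and 8 lower adjusted over the list alone). Stress response genes had a median of -0.29 (camera adjusted p = 9.37e-04). DDIT3 fell again (-1.94 ± 0.24). Of 24 p53 target genes at 8 h, 4 were lower and 20 not called (6 lower adjusted over the list alone). P53 target genes had a median of -0.35 (camera adjusted p = 0.175). Of 8 anti-apoptotic genes at 8 h, 4 were higher and 4 not called (5 higher adjusted over the list alone). Anti-apoptotic genes had a median of 0.44 (-0.53 with spike-in scaling, camera adjusted p = 0.0255, adjusted p = 0.126 with an estimated correlation). CFLAR rose (0.76 ± 0.16), but its direction was opposite with spike-in scaling (-0.20) and in limma on log2 TPM (-0.16). Of 38 genes of the G2/M list at 8 h, 1 was higher, 12 lower and 25 not called (1 higher and 14 lower adjusted over the list alone). Genes of the G2/M list had a median of -0.39 (camera adjusted p = 1.8e-04, adjusted p = 0.55 with an estimated correlation). CENPE, TTK and CCNA2 fell (-1.72 ± 0.39, -1.67 ± 0.48 and -1.48 ± 0.27). Of 22 epithelial and pancreatic carcinoma markers at 4 h, 2 were lower and 20 not called (3 lower adjusted over the list alone). Epithelial and pancreatic carcinoma markers had a median of -0.02 (camera adjusted p = 0.461). Of 79 PSN1 ribosomal protein mRNAs at 8 h, 78 were higher and 1 not called (79 higher adjusted over the list alone). PSN1 ribosomal protein mRNAs had a median of 0.63 (-0.34 with spike-in scaling, camera adjusted p = 2.58e-50, adjusted p = 0.0758 with an estimated correlation).

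KB-0742 was set against vehicle in PSN1. HEXIM1 fell at 4 h and 8 h (-1.57 ± 0.37 and -1.76 ± 0.40), to 3.38 ± 2.19 CPM from 11.1 ± 4.51 at 8 h. CCNT1 rose (1.74 ± 0.24 and 1.76 ± 0.25), as did CCNT2 (1.72 ± 0.29 and 2.13 ± 0.29), and POLR2A fell (-1.30 ± 0.20 and -1.72 ± 0.20). The DNA repair gene BRCA1 fell at 8 h (-2.67 ± 0.36). MYC was not called at 4 h (239 ± 13.3 against 267 ± 21.8 CPM) or 8 h (285 ± 70.1 against 229 ± 33.2 CPM).

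Called genes numbered 2983 at 4 h (1412 higher, 1571 lower) and 3767 at 8 h (1880, 1887). Spike-in scaling shifted the median gene by -0.92 and -0.94 and gave 74 higher and 5269 lower, and 150 higher and 5834 lower. Among the highest changes at 4 h were HELLPAR (3.46 ± 0.28) and DCAF4L1 (2.67 ± 0.32), and the lowest were NINL (-4.70 ± 0.41), RAB11FIP1P1 (-4.52 ± 0.58), RSKR (-3.62 ± 0.33) and ZMIZ1-AS1 (-3.61 ± 0.68). Among the highest at 8 h were SNORD3A (count ratio 44, 14.6 to 217), HELLPAR (4.29 ± 0.28) and DCAF4L1 (3.21 ± 0.32), and the lowest were GTF2H2B (-3.39 ± 0.82), RNPC3 (-3.32 ± 0.35), YAE1 (-3.23 ± 0.30) and BOLA1 (-3.13 ± 0.40). RNPC3 encodes a protein of the minor spliceosome.

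Of 48 splicing factors in PSN1 at 8 h, 25 were higher, 4 lower and 19 not called (25 higher and 5 lower adjusted over the list alone). Splicing factors in PSN1 had a median of 0.45 (-0.45 with spike-in scaling, camera adjusted p = 2.24e-06, adjusted p = 0.0739 with an estimated correlation). U2AF2 (1.79 ± 0.20) and PRPF3 (1.73 ± 0.17) rose the most. Of 22 genes of P-TEFb and elongation factors at 8 h, 11 were higher, 4 lower and 7 not called (11 higher and 5 lower adjusted over the list alone). Genes of P-TEFb and elongation factors had a median of 0.39 (-0.53 with spike-in scaling, camera adjusted p = 0.0103, adjusted p = 0.0708 with an estimated correlation). AFF4, a scaffold of the super elongation complex, rose (1.91 ± 0.15), and MEPCE, which caps 7SK RNA, fell (-1.98 ± 0.36). Of 34 DNA repair genes at 4 h, 9 were lower and 25 not called (9 lower adjusted over the list alone). DNA repair genes had a median of -0.53 (camera adjusted p = 0.0233, adjusted p = 0.416 with an estimated correlation). Of 43 replication genes at 8 h, 3 were higher, 17 lower and 23 not called (5 higher and 18 lower adjusted over the list alone). Replication genes had a median of -0.40 (camera adjusted p = 0.0114, adjusted p = 0.55 with an estimated correlation). CCNE2 and RFC4 fell the most (-3.41 ± 0.79 and -2.69 ± 0.25). Of 6 nuclear long noncoding RNAs at 4 h, 3 were lower and 3 not called (3 lower adjusted over the list alone). Nuclear long noncoding RNAs had a median of -0.53 (camera adjusted p = 0.0309, adjusted p = 0.339 with an estimated correlation). Of 13 mitochondrial mRNAs at 4 h, 13 were higher (13 higher adjusted over the list alone). Mitochondrial mRNAs had a median of 0.69 (-0.17 with spike-in scaling, camera adjusted p = 3.5e-10, adjusted p = 0.126 with an estimated correlation).

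Set against KB-0742 at matched times in PSN1, KI-CDK9d-32 gave lower MYC at 4 h and 8 h (-0.82 ± 0.14 and -0.56 ± 0.14) and lower CCNT1 (-1.30 ± 0.24 and -1.44 ± 0.25). KLF6, an immediate-early transcription factor gene, was higher at 8 h (2.92 ± 0.26), as was CFLAR, which encodes an inhibitor of caspase-8 (1.75 ± 0.17). MCL1 was higher (0.74 ± 0.20), and MDM2, whose product restrains p53, was lower (-2.13 ± 0.26).

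Genes differing between the compounds numbered 2175 at 4 h (1243 higher with KI-CDK9d-32, 932 lower) and 3094 at 8 h (1494, 1600). The spike-in shift of the median was 0.27 and 0.01, with 1091 higher and 227 lower, and 644 higher and 883 lower called under spike-in scaling. At 4 h the highest changes were LHFPL4 (6.45 ± 0.51), RAB11FIP1P1 (4.29 ± 0.59), NINL (4.21 ± 0.42), TNFRSF13C (4.02 ± 0.37) and LINC00862 (3.79 ± 0.48), and the lowest were UGCG (-2.73 ± 0.36), MPRIP-AS1 (-2.71 ± 0.27), TRIM11 (-2.69 ± 0.28) and MATR3 (-2.62 ± 0.71). The highest at 8 h were RNPC3 (3.58 ± 0.35), LHFPL4 (3.33 ± 0.36) and CD44-DT (3.27 ± 0.39), and the lowest were RPL21P28 (-3.14 ± 0.33), BAP1 (-2.69 ± 0.20) and CTSZ (-2.61 ± 0.17). UGCG encodes glucosylceramide synthase, BAP1 a deubiquitinase and CTSZ a cathepsin.

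Of 64 MYC target genes at 8 h, 2 were higher, 23 lower and 39 not called (4 higher and 25 lower adjusted over the list alone). MYC target genes had a median of -0.21 (camera adjusted p = 1.18e-04, adjusted p = 0.39 with an estimated correlation). WDR43 (-2.43 ± 0.24), PPRC1 (-1.87 ± 0.29) and MPHOSPH10 (-1.67 ± 0.30) were the lowest. Of 48 PSN1 splicing factor genes at 8 h, 5 were higher, 23 lower and 20 not called (5 higher and 23 lower adjusted over the list alone). PSN1 splicing factor genes had a median of -0.24 (camera adjusted p = 9.12e-07, adjusted p = 0.0708 with an estimated correlation). Of 16 snoRNA-host RNAs in PSN1 at 4 h, 1 was higher, 7 lower and 8 not called (1 higher and 8 lower adjusted over the list alone). SnoRNA-host RNAs in PSN1 had a median of -0.26 (camera adjusted p = 8.02e-06, adjusted p = 0.0758 with an estimated correlation).

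In RH4, an established fusion-positive rhabdomyosarcoma line, the degrader was compared with vehicle at 4 h and 8 h. MYC fell at 4 h (-1.11 ± 0.24), from 30.2 ± 8.23 to 13.8 ± 6.05 CPM, together with the immediate-early gene DUSP1 (-1.49 ± 0.34), whose call was lost without RH4 vehicle 4 h replicate 2 (adjusted p = 0.0698). DDIT4 and DDIT3 fell at 4 h (-1.84 ± 0.35 and -1.52 ± 0.22) and 8 h (-2.01 ± 0.34 and -1.81 ± 0.22). POLR2A fell at 8 h (-0.69 ± 0.14), and the muscle regulator gene MYOG fell with it (-0.90 ± 0.11).

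Called genes numbered 646 at 4 h (418 higher, 228 lower) and 1838 at 8 h (1108, 730). The 4 h count was 329 without RH4 KI-CDK9d-32 4 h replicate 1, 374 without RH4 vehicle 4 h replicate 2, 405 without RH4 vehicle 4 h replicate 1 and 421 without RH4 vehicle 4 h replicate 4. TUBA1B-AS1 was not called without any 1 of 3 libraries (highest adjusted p = 0.105, without RH4 vehicle 4 h replicate 2), and NT5DC3 was not called without RH4 vehicle 4 h replicate 1 (adjusted p = 0.0599). Spike-in scaling shifted the median gene by -0.36 and -0.92 and gave 16 higher and 89 lower, and 89 higher and 6222 lower. The highest changes at 4 h were LHFPL4 (4.52 ± 0.33), SNORD3B-2 (2.49 ± 0.48), SNORD3B-1 (2.45 ± 0.53), TUBA1B-AS1 (1.92 ± 0.50) and APCDD1L-DT (1.91 ± 0.38), and the lowest were DDIT4 (-1.84 ± 0.35), NT5DC3 (-1.61 ± 0.36), DDIT3 (-1.52 ± 0.22) and DUSP1 (-1.49 ± 0.34). At 8 h the highest were LHFPL4 (4.72 ± 0.31), SNORD3B-2 (4.06 ± 0.51), SNORD3B-1 (3.59 ± 0.54) and PCGF3-AS1 (2.87 ± 0.32), and the lowest were PLK2 (-2.07 ± 0.34), DDIT4 (-2.01 ± 0.34), MEIS1 (-1.92 ± 0.33), DDIT3 (-1.81 ± 0.22) and GNB1L (-1.76 ± 0.28). PLK2 encodes a polo-like kinase and MEIS1 a homeobox transcription factor.

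Of 27 immediate-early list members in RH4 at 4 h, 5 were lower and 22 not called (1 higher and 7 lower adjusted over the list alone). Immediate-early list members in RH4 had a median of -0.61 (camera adjusted p = 5.33e-06). Of 22 stress response genes in RH4 at 8 h, 1 was higher, 5 lower and 16 not called (1 higher and 8 lower adjusted over the list alone). Stress response genes in RH4 had a median of -0.38 (camera adjusted p = 1.14e-04). Of 26 myogenic and fusion-positive rhabdomyosarcoma markers at 8 h, 7 were higher, 2 lower and 17 not called (9 higher and 2 lower adjusted over the list alone). Myogenic and fusion-positive rhabdomyosarcoma markers had a median of 0.28 (-0.61 with spike-in scaling, camera adjusted p = 0.2). The cadherin gene CDH15 rose (0.72 ± 0.11, or -0.18 with spike-in scaling, the opposite direction). Of 13 RH4 mitochondrially encoded mRNAs at 8 h, 13 were higher (13 higher adjusted over the list alone). RH4 mitochondrially encoded mRNAs had a median of 0.77 (-0.13 with spike-in scaling, camera adjusted p = 1.0e-26). Of 79 RH4 ribosomal protein mRNAs at 8 h, 79 were higher (79 higher adjusted over the list alone). RH4 ribosomal protein mRNAs had a median of 0.63 (-0.27 with spike-in scaling, camera adjusted p = 1.01e-82).

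KB-0742 against vehicle in RH4 lowered HEXIM1 at 4 h and 8 h (-2.09 ± 0.47 and -1.38 ± 0.44), from 9.84 ± 3.55 to 2.27 ± 1.19 CPM at 4 h. CCNT1 rose (1.41 ± 0.24 and 2.61 ± 0.24), as did MCL1 (1.18 ± 0.29 and 1.11 ± 0.28), and CDK9 rose at 8 h (1.48 ± 0.31). POLR2A fell (-0.59 ± 0.15 and -1.13 ± 0.15). The growth-arrest gene BTG2 fell (-1.93 ± 0.51 and -3.15 ± 0.60) while CCN1, which encodes a matrix protein, rose (1.61 ± 0.29 and 3.11 ± 0.29). With spike-in scaling MCL1 (-0.46) and CDK9 (-0.06) took the opposite direction at 8 h, and at 4 h MCL1 was 0.10 and CCNT1 0.35.

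Called genes numbered 3815 at 4 h (1854 higher, 1961 lower) and 5480 at 8 h (2715, 2765). Spike-in scaling shifted the median gene by -1.12 and -1.66 and gave 61 higher and 7458 lower, and 121 higher and 9388 lower. Among the highest changes at 4 h were MPRIP-AS1 (2.74 ± 0.24), APCDD1L-DT (2.66 ± 0.38) and HELLPAR (2.60 ± 0.17), and the lowest were NINL (-3.49 ± 0.28), LINC00339 (-3.31 ± 0.33), MED31 (-3.14 ± 0.37) and RSKR (-3.11 ± 0.33). MED31 encodes a subunit of the Mediator complex. Among the highest at 8 h were APCDD1L-DT (4.20 ± 0.36) and HELLPAR (4.12 ± 0.17), and the lowest were UPK3BL1 (at least 105-fold lower), MED31 (-4.65 ± 0.49) and ST3GAL3 (-4.01 ± 0.77). ST3GAL3 encodes a sialyltransferase.

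Of 35 RH4 DNA repair genes at 4 h, 15 were lower and 20 not called (16 lower adjusted over the list alone). RH4 DNA repair genes had a median of -0.53 (camera adjusted p = 6.09e-04). FANCL, BRIP1 and FANCB of the Fanconi anemia pathway fell the most (-2.14 ± 0.26, -2.09 ± 0.44 and -1.79 ± 0.51). Of 48 splicing factors in RH4 at 8 h, 26 were higher, 8 lower and 14 not called (26 higher and 9 lower adjusted over the list alone). Splicing factors in RH4 had a median of 0.56 (-1.04 with spike-in scaling, camera adjusted p = 3.06e-06). PRPF3 (1.75 ± 0.12) and SON (1.62 ± 0.09) rose and SRSF5 fell (-1.73 ± 0.15). Of 16 snoRNA-host RNAs in RH4 at 8 h, 12 were higher, 1 lower and 3 not called (12 higher and 1 lower adjusted over the list alone). SnoRNA-host RNAs in RH4 had a median of 0.79 (-0.80 with spike-in scaling, camera adjusted p = 2.99e-09). SNHG17 and SNHG15 rose the most (1.98 ± 0.12 and 1.76 ± 0.13). Of 12 RNA polymerase II subunit genes at 4 h, 7 were higher, 1 lower and 4 not called (7 higher and 1 lower adjusted over the list alone). RNA polymerase II subunit genes had a median of 0.56 (-0.48 with spike-in scaling, camera adjusted p = 0.00344, adjusted p = 0.0858 with an estimated correlation). Of 45 RH4 replication and E2F target genes at 8 h, 9 were higher, 22 lower and 14 not called (9 higher and 23 lower adjusted over the list alone). RH4 replication and E2F target genes had a median of -0.59 (camera adjusted p = 0.00208, adjusted p = 0.0935 with an estimated correlation). RFC4, POLE2 and PCNA fell (-3.42 ± 0.25, -3.03 ± 0.44 and -2.55 ± 0.15). Of 79 RH4 cytosolic ribosomal protein mRNAs at 8 h, 79 were higher (79 higher adjusted over the list alone). RH4 cytosolic ribosomal protein mRNAs had a median of 1.16 (-0.43 with spike-in scaling, camera adjusted p = 8.5e-86).

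Between the compounds in RH4, MYC was lower with KI-CDK9d-32 at 4 h (-1.25 ± 0.25, or -0.50 with spike-in scaling) and HEXIM1 was higher at 4 h and 8 h (1.98 ± 0.47 and 1.52 ± 0.44). MYCN, which was counted above the filter in RH4 alone, was lower at 8 h (-1.68 ± 0.59), a call lost without any 1 of 4 libraries (highest adjusted p = 0.118, without RH4 KB-0742 8 h replicate 4). CCNT1 was lower at 4 h and 8 h (-1.47 ± 0.24 and -2.01 ± 0.24), and the stress gene DDIT3 was lower (-2.65 ± 0.23). BRCA1 and FANCL were higher (1.99 ± 0.30 and 2.04 ± 0.30).

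Genes differing numbered 3114 at 4 h (1621 higher with KI-CDK9d-32, 1493 lower) and 4635 at 8 h (2302, 2333). The spike-in shift of the median was 0.72 and 0.71, with 4128 higher and 150 lower, and 4419 higher and 361 lower called under spike-in scaling. The highest changes at 4 h were LHFPL4 (4.04 ± 0.34), TRIM66 (3.57 ± 0.30), OGFOD2 (3.28 ± 0.42) and LINC00339 (3.24 ± 0.33), and the lowest were MPRIP-AS1 (-3.23 ± 0.25) and IGF2BP2-AS1 (-2.70 ± 0.35). At 8 h the highest were UPK3BL1 (at least 51.1-fold higher), ST3GAL3 (5.15 ± 0.72), LHFPL4 (4.84 ± 0.36) and MED31 (4.51 ± 0.50), and the lowest were MPRIP-AS1 (-4.07 ± 0.27), ZNF557 (-3.19 ± 0.27), PLK2 (-2.97 ± 0.34) and FAM215B (-2.97 ± 0.20).

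Of 48 RH4 splicing factor genes at 8 h, 6 were higher, 27 lower and 15 not called (7 higher and 28 lower adjusted over the list alone). RH4 splicing factor genes had a median of -0.44 (0.26 with spike-in scaling, camera adjusted p = 3.06e-09). Of 16 RH4 snoRNA-host RNAs at 8 h, 10 were lower and 6 not called (10 lower adjusted over the list alone). RH4 snoRNA-host RNAs had a median of -0.54 (0.15 with spike-in scaling, camera adjusted p = 2.55e-08). Of 27 RH4 immediate-early genes at 4 h, 1 was higher, 12 lower and 14 not called (1 higher and 12 lower adjusted over the list alone). RH4 immediate-early genes had a median of -0.71 (camera adjusted p = 1.36e-06). Of 35 repair genes in RH4 at 4 h, 13 were higher, 1 lower and 21 not called (13 higher and 1 lower adjusted over the list alone). Repair genes in RH4 had a median of 0.48 (camera adjusted p = 0.00196).

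**Figure D3:**
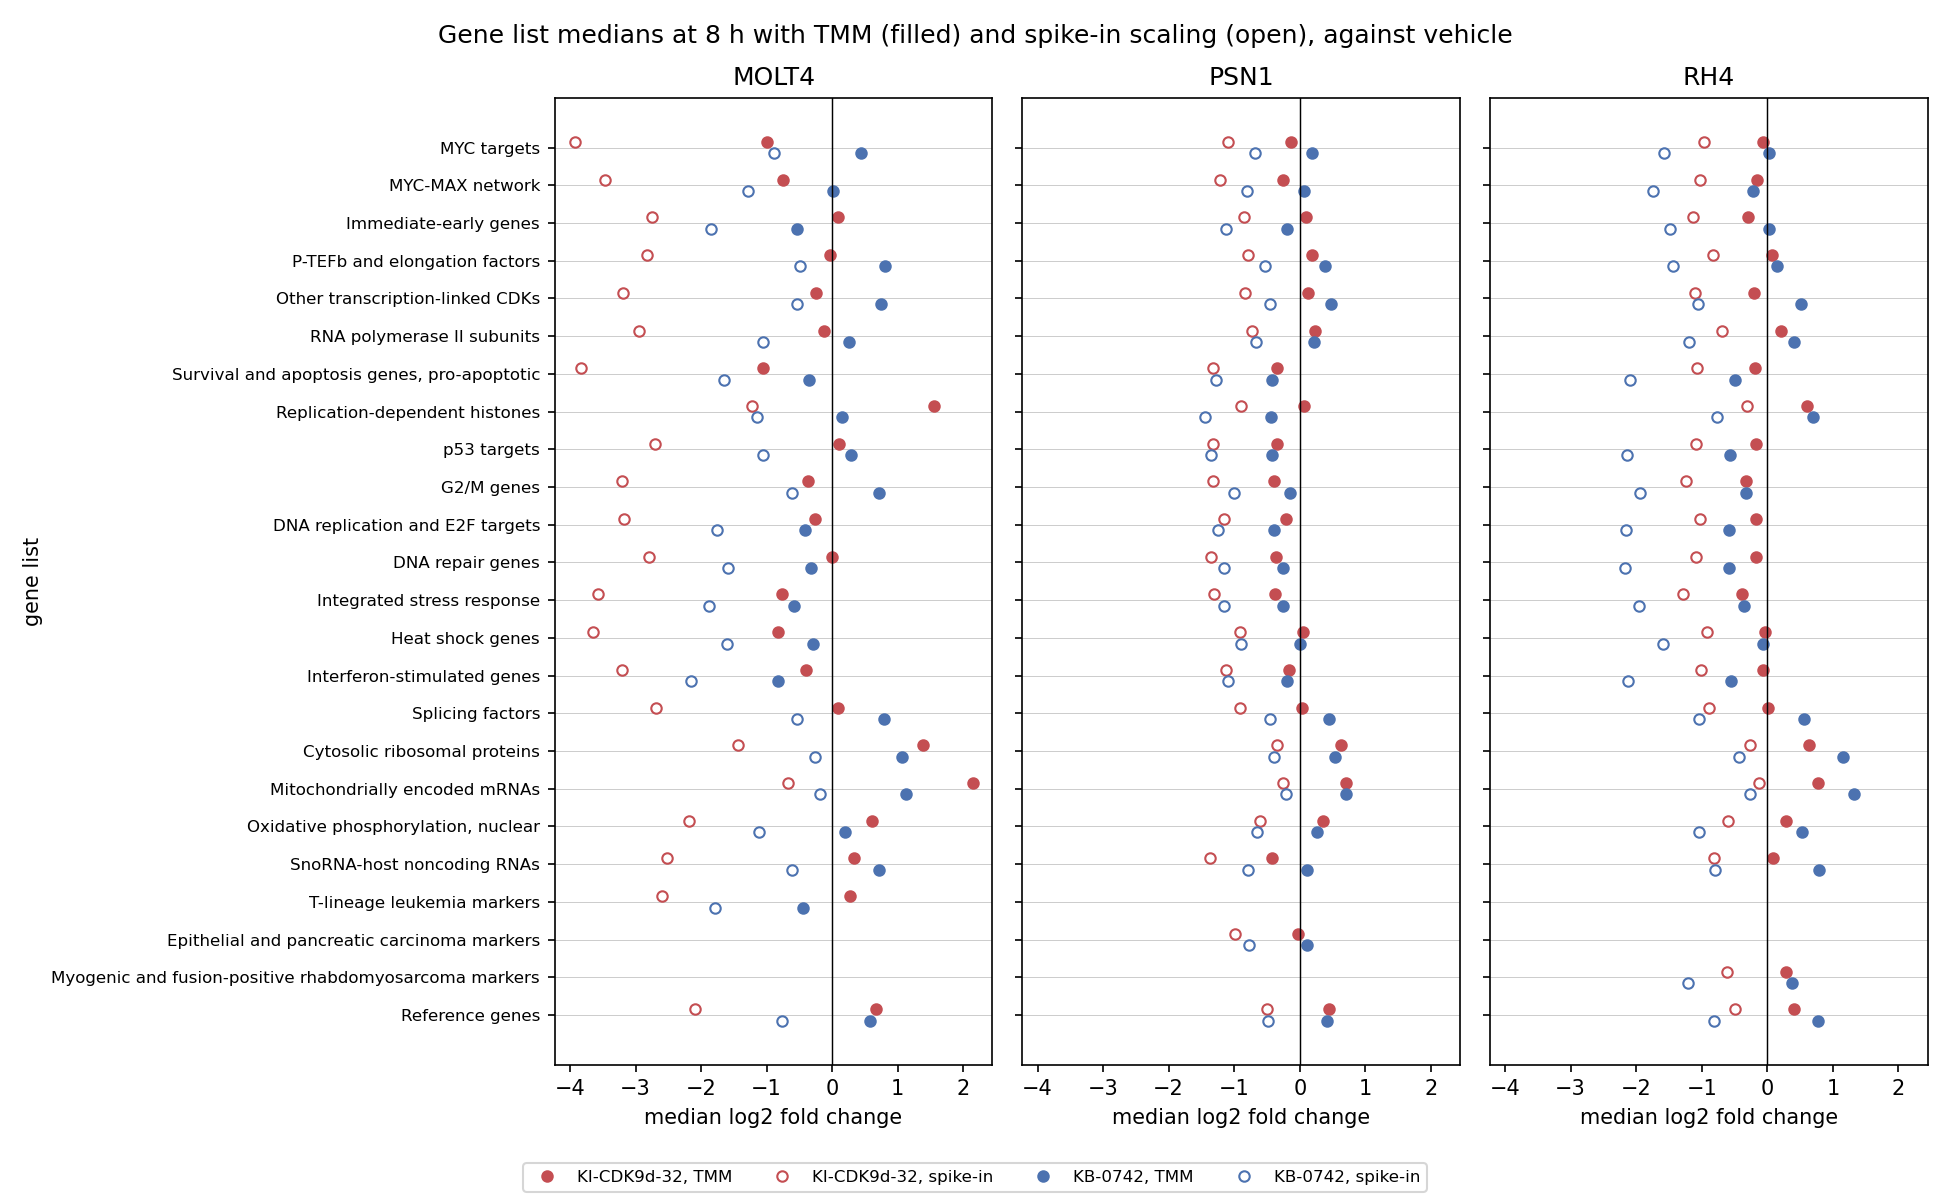
Median log2 fold change of each gene list at 8 h against vehicle, for KI-CDK9d-32 and KB-0742 in the 3 lines, with TMM scaling (filled) and spike-in scaling (open), for lists with at least 10 tested members. MOLT4 ribosomal protein mRNAs with KI-CDK9d-32 had a median of 1.39 with TMM scaling and -1.44 with spike-in scaling, a change of direction.

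Whether an effect changed between 4 h and 8 h was tested as the difference of the 2 differences from vehicle. In MOLT4 the fall of MYC with KI-CDK9d-32 became smaller (0.86 ± 0.24, or -0.89 with spike-in scaling, the opposite direction), and the rise of MYC with KB-0742 was lost (-1.05 ± 0.21). The MYC change with KI-CDK9d-32 was not called without any 1 of 2 libraries (highest adjusted p = 0.0597, without MOLT4 vehicle 4 h replicate 1). CCNT1 rose further with KB-0742 in RH4 (1.20 ± 0.34), a call lost without any 1 of 3 libraries (highest adjusted p = 0.0687, without RH4 vehicle 4 h replicate 2). The effect of KI-CDK9d-32 differed between the times for 1459 genes in MOLT4 (601 higher at 8 h, 858 lower) and that of KB-0742 for 2071 (910, 1161). With spike-in scaling these became 8 higher and 5294 lower for KI-CDK9d-32, with a median shift of -1.79. For KB-0742 the shift was 0.01, and edgeR with spike-in scaling called 0 genes (888 at an unadjusted p below 0.05), where DESeq2 called 2438 and limma 801 with other scalings. In PSN1 KB-0742 gave 235 such genes (163, 72), or 154 without PSN1 vehicle 4 h replicate 1, and 2 with spike-in scaling. KI-CDK9d-32 gave 2 in PSN1 (1, 1), or between 0 and 6 when 1 library was left out. The PSN1 libraries that moved this last count gave 0 without PSN1 vehicle 4 h replicate 1, 0 without PSN1 KI-CDK9d-32 4 h replicate 3, 0 without PSN1 KI-CDK9d-32 8 h replicate 4, 0 without PSN1 vehicle 4 h replicate 4, 0 without PSN1 KI-CDK9d-32 4 h replicate 4, 5 without PSN1 KI-CDK9d-32 4 h replicate 1 and 6 without PSN1 KI-CDK9d-32 8 h replicate 1. Where edgeR called 0 of these, 1053 to 1153 genes had an unadjusted p below 0.05, and on all libraries DESeq2 called 60 and limma 21. In RH4 KB-0742 gave 1027 (531, 496), and spike-in scaling gave 2 higher and 303 lower. The edgeR test called 0 genes for KI-CDK9d-32 in RH4, where 891 had an unadjusted p below 0.05, DESeq2 called 65 and limma 25. Leaving out 1 library there gave 1 without RH4 vehicle 8 h replicate 1, 1 without RH4 KI-CDK9d-32 8 h replicate 1, 2 without RH4 vehicle 4 h replicate 4 and 3 without RH4 KI-CDK9d-32 4 h replicate 1.

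Genes called in the same direction with both compounds at 8 h numbered 994 higher and 1183 lower in MOLT4, 729 and 505 in PSN1, and 770 and 409 in RH4. Independence of the 2 sets of calls gave 568 and 865, 208 and 181, and 249 and 167. With spike-in scaling at most 71, 139 and 89 were higher with both compounds. Shared vehicle libraries by themselves correlate the log2 fold changes. In 20 simulations without treatment effects their mean correlation was 0.427, 0.47 and 0.46, above the measured 0.235, 0.397 and 0.351. Their mean covariance was 0.139, 0.14 and 0.126, below the measured 0.511, 0.418 and 0.328. With the vehicle libraries split between the compounds, 729 to 752 higher and 855 to 885 lower genes were shared in MOLT4, 353 to 398 and 240 to 282 in PSN1, and 460 to 527 and 161 to 219 in RH4, where independence in the same fits gave at most 382 and 633, 149 and 122, and 138 and 84. Genes called in opposite directions numbered 1083 in MOLT4, 132 in PSN1 and 141 in RH4 (1411, 389 and 418 by independence). With the vehicle libraries split they numbered 760 to 838, 72 to 162 and 60 to 105, where independence in the same fits gave 955 to 989, 177 to 271 and 185 to 223. Of the 1083, 736 were lower with KI-CDK9d-32 and higher with KB-0742 and 347 the reverse (785 and 626 by independence).

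**Figure D4:**
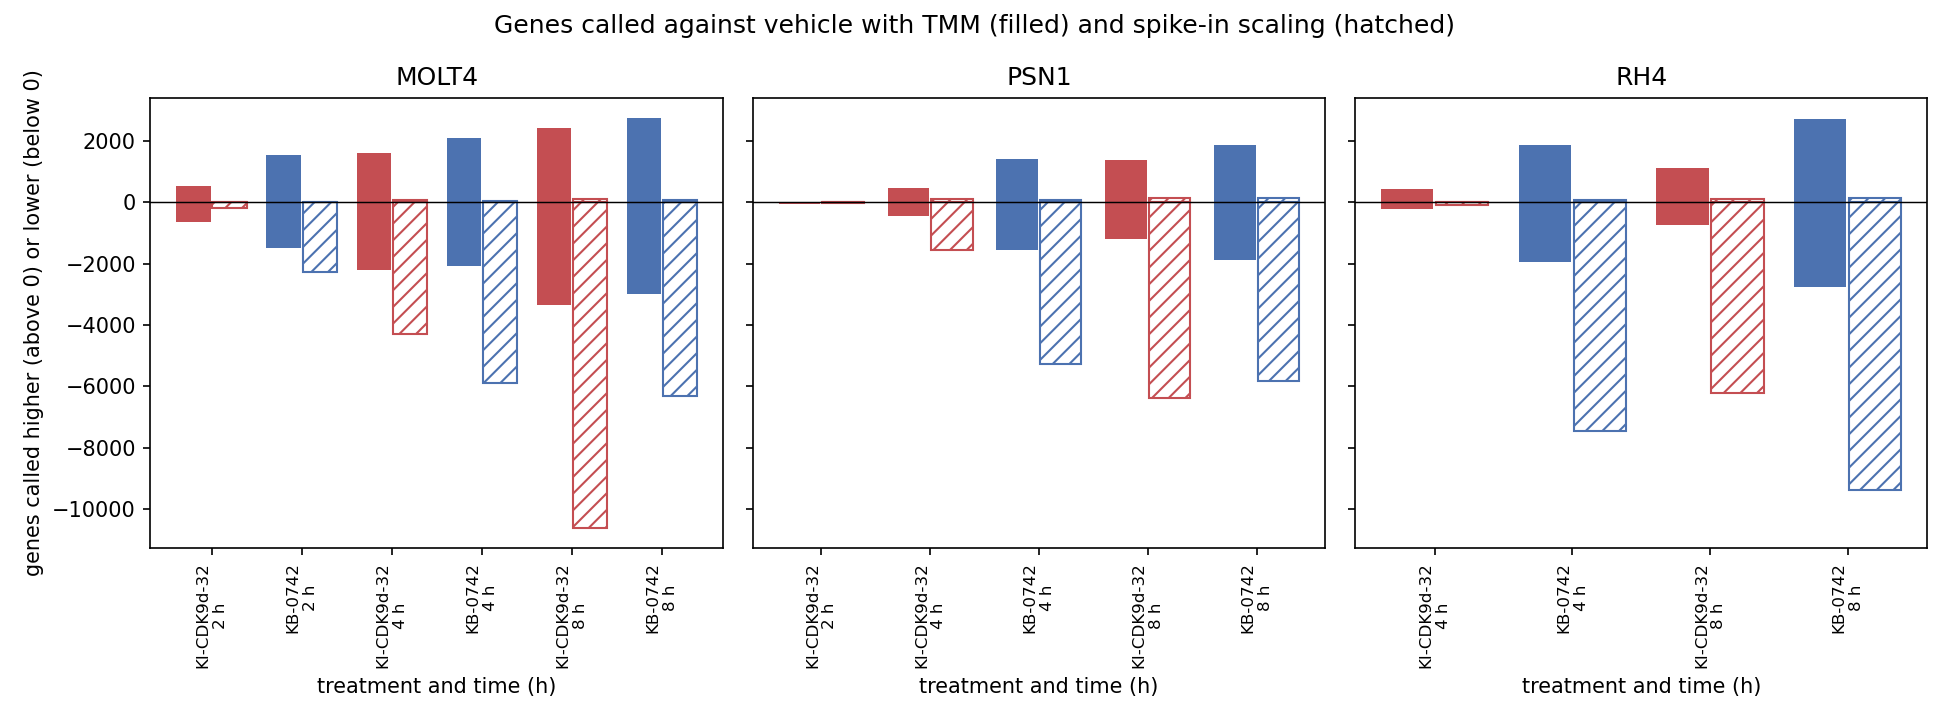
Genes called higher (above 0) and lower (below 0) against vehicle at each time in the 3 lines, with TMM scaling and with spike-in scaling. With spike-in scaling 10609 genes were lower with KI-CDK9d-32 in MOLT4 at 8 h, against 3353 with TMM scaling.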

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

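Tests here were fixed before their results were seen. Later, a condition on MOLT4 replicate 3, itself noticed in the data first, was set aside. A library was singled out where its distance to the nearest other library of its group of 4 took up nearly all of the group's range. Of 66 sets of 4 values (spike-in shares, mitochondrial shares and MYC), 5 went beyond the 95% limit, and chance does so in about 1 in 20 sets. The spike-in share of MOLT4 KB-0742 4 h replicate 3 was 49.4% against 16.31 to 20.88% in the other 3 libraries. MOLT4 vehicle 8 h replicate 4 had a spike-in share of 11.7% against 15.26 to 15.81%, and PSN1 KB-0742 8 h replicate 4 one of 22.4% against 14.65 to 15.95%. The mitochondrial share of MOLT4 KI-CDK9d-32 8 h replicate 1 was 26.3% against 22.93 to 23.49%, and that of RH4 KB-0742 8 h replicate 3 was 33.2% against 28.57 to 29.19%.

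In MOLT4, replicate 3 had the highest spike-in share of its group with KI-CDK9d-32 at 4 h (39.5%) and 8 h (61.5%) and with KB-0742 at 4 h (49.4%), but not with KB-0742 at 8 h (21.8% in a group of 18.97 to 24.97%). Less cell RNA in the lysate of these wells is a candidate explanation, under which the slope of the library on the change fitted without it would lie within the range of the other 3 replicates, and it did so in 1 of 4 groups (KI-CDK9d-32 at 4 h, 0.689 in a range of 0.673 to 0.696). A stronger response to the compound in these wells is the other, and there the slope lay above all other replicates in 2 of 4 groups (0.71 against at most 0.704 with KB-0742 at 4 h, and 0.84 against at most 0.816 with KI-CDK9d-32 at 8 h), and below the highest other in the other 2 (0.689 against 0.696 with KI-CDK9d-32 at 4 h, and 0.667 against 0.952 with KB-0742 at 8 h). Those 2 groups meet the condition set in advance against a stronger response. It was later set aside, as the first difference is smaller than the other replicates' range and KB-0742 at 8 h lacks the high share. The explanations cannot be told apart, as each range rests on 3 libraries. A shared batch of these wells was not tested, as the labels give none.

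The effect of a compound differed between 4 h and 8 h by the test of the difference for 1459 genes with KI-CDK9d-32 and 2071 with KB-0742 in MOLT4, 2 and 235 in PSN1, and 1027 with KB-0742 in RH4. To test chance, the times were shuffled within each treatment, without regard to replicate number, in 50 arrangements, the real one included, in fits to the libraries of these groups alone. Few arrangements gave as many genes for KI-CDK9d-32 in MOLT4 (1290 genes, highest other 1388, 2 of 50 as large). The same held for KB-0742 in MOLT4 (2190, highest other 2133, 1 of 50) and in RH4 (837, highest other 860, 2 of 50). The shuffle also removes any change with time that compound and vehicle share. These 3 results thus argue against no difference between the times at all, but cannot exclude chance for a changed effect. Chance cannot be excluded for KB-0742 in PSN1 (114, highest other 229, 3 of 50) or for KI-CDK9d-32 in RH4 (1, highest other 53, 10 of 50). For KI-CDK9d-32 in PSN1 edgeR called 0 genes in this fit (938 at an unadjusted p below 0.05), so that 50 of 50 are as large by definition and the shuffle decides nothing (highest other 86). The highest other arrangement kept the 4 compound libraries of 1 time together in 5 of these 6 sets, and in PSN1 KB-0742 and RH4 KI-CDK9d-32 it differed from the real one in the times of vehicle libraries alone. In the sixth, PSN1 KI-CDK9d-32, it parted compound replicates 1 and 2 from 3 and 4, which points to a structure by replicate number.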

How the results depend on the processing

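The setting without the 6 libraries of MOLT4 replicate 3 and the test of same-number spike-in shares were chosen only after the shares were seen, and the other tests of this part were planned. Counts in parentheses after a comparison or line are those reported, and a compound at 1 time is compared with vehicle unless KB-0742 is named. Depth and 4 replicates limit the calls of small changes. In data simulated for KI-CDK9d-32 against vehicle at 8 h, the test recovered 28% of genes raised 1.5-fold, 54% at 2-fold, 96% at 4-fold and 80% at 0.25-fold in MOLT4 (50 genes each of 11664). The same 4 shares were 14, 50, 88 and 82% in PSN1 (of 12471 genes) and 24, 60, 98 and 90% in RH4 (of 12058).

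Scaling to the spike-ins sets each library by RNA per lysate in place of its other genes, which by construction moves the log2 fold changes of a comparison together, less so for genes with counts near 0. Called genes became 213 for MOLT4 KI-CDK9d-32 at 2 h (1164), 10709 for MOLT4 KI-CDK9d-32 at 8 h (5781) and 485 for MOLT4 KI-CDK9d-32 against KB-0742 at 2 h (2138). Under this scaling there were 1639 for MOLT4 KI-CDK9d-32 against KB-0742 at 4 h (4164), 5302 for MOLT4 KI-CDK9d-32 from 4 h to 8 h (1459) and 0 for MOLT4 KB-0742 from 4 h to 8 h (2071). In PSN1 there were 15 for PSN1 KI-CDK9d-32 at 2 h (60), 1645 for PSN1 KI-CDK9d-32 at 4 h (918) and 6521 for PSN1 KI-CDK9d-32 at 8 h (2576). It gave 5343 for PSN1 KB-0742 at 4 h (2983), 5984 for PSN1 KB-0742 at 8 h (3767) and 1318 for PSN1 KI-CDK9d-32 against KB-0742 at 4 h (2175). Others were 1527 for PSN1 KI-CDK9d-32 against KB-0742 at 8 h (3094), 0 for PSN1 KI-CDK9d-32 from 4 h to 8 h (2) and 2 for PSN1 KB-0742 from 4 h to 8 h (235). For RH4 it gave 105 for RH4 KI-CDK9d-32 at 4 h (646), 6311 for RH4 KI-CDK9d-32 at 8 h (1838) and 7519 for RH4 KB-0742 at 4 h (3815). Last were 9509 for RH4 KB-0742 at 8 h (5480), 1 for RH4 KI-CDK9d-32 from 4 h to 8 h (0) and 305 for RH4 KB-0742 from 4 h to 8 h (1027). Where edgeR called 0 genes here, the unadjusted p lay below 0.05 for 888 genes in MOLT4 and 753 in PSN1. Calls shared by both compounds at 8 h rose to 6170 in MOLT4 (2177), 4037 in PSN1 (1234) and 5641 in RH4 (1179).

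Genes and lists that were called and took the opposite sign with spike-in scaling follow. They were, in MOLT4 KI-CDK9d-32 at 8 h -1.95 for CCNT1, -0.50 for HSPB1, -1.44 for ribosomal proteins, -0.68 for mitochondrial mRNAs, -2.10 for reference genes and -1.22 for histones, MOLT4 KB-0742 at 2 h -0.06 for CCNT1 and MOLT4 KB-0742 at 4 h -0.28 for MYC and -0.60 for nuclear oxidative phosphorylation. Others were, in MOLT4 KB-0742 at 8 h -0.17 for CDK9, -0.11 for SNHG15, -0.18 for SNHG16, -0.27 for ribosomal proteins, -0.62 for G2/M genes, -0.54 for other CDKs, -0.61 for snoRNA hosts and -0.53 for splicing factors, MOLT4 KI-CDK9d-32 against KB-0742 at 8 h -0.88 for T-lineage markers and MOLT4 KI-CDK9d-32 from 4 h to 8 h -0.89 for MYC. Still others were, in PSN1 KI-CDK9d-32 at 8 h -0.20 for CFLAR, -0.35 for MCL1, -0.34 for ribosomal proteins and -0.53 for anti-apoptotic genes, PSN1 KB-0742 at 4 h -0.17 for mitochondrial mRNAs and PSN1 KB-0742 at 8 h -0.53 for P-TEFb and elongation factors and -0.45 for splicing factors. RH4 had, in RH4 KI-CDK9d-32 at 8 h -0.18 for CDH15, -0.27 for ribosomal proteins and -0.13 for mitochondrial mRNAs, RH4 KB-0742 at 4 h -0.48 for RNA polymerase II subunits and RH4 KB-0742 at 8 h -0.06 for CDK9, -0.46 for MCL1, -0.43 for ribosomal proteins, -0.80 for snoRNA hosts and -1.04 for splicing factors. The last were, in RH4 KI-CDK9d-32 against KB-0742 at 8 h 0.15 for snoRNA hosts and 0.26 for splicing factors. Of the other gene values 236 kept direction and call and 44 kept direction only, and of the other list medians 2 stayed within and 31 moved beyond the spread between replicates, some of these across 0 where the list was not called.

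The TPM values were computed with the spike-ins in their total, so limma on deposited log2 TPM carries part of the same shift by construction. Its counts were 5703 for MOLT4 KI-CDK9d-32 at 4 h (3797), 9533 for MOLT4 KI-CDK9d-32 at 8 h (5781), 6484 for MOLT4 KB-0742 at 4 h (4174) and 3234 for MOLT4 KI-CDK9d-32 from 4 h to 8 h (1459). It also gave 801 for MOLT4 KB-0742 from 4 h to 8 h (2071), 116 for PSN1 KI-CDK9d-32 at 2 h (60), 1749 for PSN1 KI-CDK9d-32 at 4 h (918) and 4731 for PSN1 KI-CDK9d-32 at 8 h (2576). Moreover it gave 21 for PSN1 KI-CDK9d-32 from 4 h to 8 h (2), 72 for PSN1 KB-0742 from 4 h to 8 h (235), 4689 for RH4 KI-CDK9d-32 at 8 h (1838) and 6258 for RH4 KB-0742 at 4 h (3815). Last came 25 for RH4 KI-CDK9d-32 from 4 h to 8 h (0). Direction changed, in MOLT4 KI-CDK9d-32 at 8 h -0.49 for CCNT1, -0.39 for ribosomal proteins, -1.03 for reference genes and -0.09 for histones, MOLT4 KB-0742 at 4 h -0.08 for MYC and -0.31 for nuclear oxidative phosphorylation, MOLT4 KB-0742 at 8 h -0.07 for SNHG15, -0.14 for G2/M genes, -0.12 for snoRNA hosts and -0.10 for splicing factors and MOLT4 KI-CDK9d-32 against KB-0742 at 8 h -0.28 for T-lineage markers. It changed too, in PSN1 KI-CDK9d-32 at 8 h -0.16 for CFLAR and -0.18 for anti-apoptotic genes, PSN1 KB-0742 at 8 h -0.12 for P-TEFb and elongation factors and -0.15 for splicing factors, RH4 KB-0742 at 4 h -0.17 for RNA polymerase II subunits and RH4 KB-0742 at 8 h -0.12 for SNHG15, -0.30 for snoRNA hosts and -0.49 for splicing factors. Lastly it changed, in RH4 KI-CDK9d-32 against KB-0742 at 8 h 0.05 for snoRNA hosts and 0.09 for splicing factors. It kept the direction of the other gene values, 20 of them no longer called.

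With the DESeq2 Wald test the counts became 126 for PSN1 KI-CDK9d-32 at 2 h (60), 60 for PSN1 KI-CDK9d-32 from 4 h to 8 h (2), 398 for PSN1 KB-0742 from 4 h to 8 h (235) and 65 for RH4 KI-CDK9d-32 from 4 h to 8 h (0). Without a low-count filter they were 22 for PSN1 KI-CDK9d-32 from 4 h to 8 h (2) and 35 for RH4 KI-CDK9d-32 from 4 h to 8 h (0). With only the groups compared in the fit they were 1776 for MOLT4 KI-CDK9d-32 at 2 h (1164), 150 for PSN1 KI-CDK9d-32 at 2 h (60), 0 for PSN1 KI-CDK9d-32 from 4 h to 8 h (2), 114 for PSN1 KB-0742 from 4 h to 8 h (235) and 1 for RH4 KI-CDK9d-32 from 4 h to 8 h (0). In that last fit edgeR had 938 genes at an unadjusted p below 0.05 where it called 0. The cause was not tested for these settings. Requiring an absolute log2 fold change of at least 1 left 992 in MOLT4, 377 in PSN1 and 241 in RH4 shared calls, by construction of a stricter threshold. DESeq2 size factors in edgeR left all 31 counts and shares where they were, within 1.5 times, and 292 gene values with direction and call, with 1 exception. List medians moved beyond the spread between replicates for 4 lists with these size factors, 4 with the Wald test, 4 without the filter and 6 with only the groups compared. With an estimated correlation, 20 of the list results were no longer called and 37 were as before. Without the 6 libraries of replicate 3 in MOLT4, 9 counts and 25 list medians were as before and 3 gene calls were lost.

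With the replicate number as a block (replicate block), counts became 138 for PSN1 KI-CDK9d-32 at 2 h (60), 1456 for PSN1 KI-CDK9d-32 at 4 h (918), 91 for PSN1 KI-CDK9d-32 from 4 h to 8 h (2), 426 for PSN1 KB-0742 from 4 h to 8 h (235), 1036 for RH4 KI-CDK9d-32 at 4 h (646) and 71 for RH4 KI-CDK9d-32 from 4 h to 8 h (0). The labels do not say that numbers pair the libraries, but as a hint from the data in 64 of 86 same-number pairs the library correlated best with its own number, where chance gives about 22 (libraries recur between comparisons), and every library did so in 3 of 22 comparisons. In RH4 replicate 1 had the highest and replicate 3 the lowest spike-in share in 6 of 6 groups. The arrangement of PSN1 KI-CDK9d-32 times that called 86 genes parted replicates 1 and 2 from the others, so a structure by replicate number is a candidate explanation for the 91 genes with the block. The cause was not tested. Spike-in shares were above vehicle in every same-number pair in 12 of 15 comparisons, among them RH4 at 8 h, by 2.67 to 4.21 percentage points with KI-CDK9d-32 and 4.42 to 6.26 with KB-0742 (exact permutation p = 0.125 each over sign flips of 4 pairs, the smallest possible).

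Leaving out 1 library at a time gave 154 to 230 for PSN1 KB-0742 from 4 h to 8 h, 0 to 6 for PSN1 KI-CDK9d-32 from 4 h to 8 h and 34 to 53 for PSN1 KI-CDK9d-32 at 2 h, and 532 to 952 for PSN1 KI-CDK9d-32 at 4 h, 0 to 3 for RH4 KI-CDK9d-32 from 4 h to 8 h and 329 to 520 for RH4 KI-CDK9d-32 at 4 h. All other counts and shares stayed within 1.5 times or their spread, as did 421 of these values in all. Of the gene values 46 lost their call and 2289 kept direction and call, and 15 list medians moved beyond the spread between replicates.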

Other observations

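Below, the tests of low input by line and of spike-in scaled mitochondrial mRNAs were chosen only after the result was seen, the others before.

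In each of the 22 comparisons of 2 groups the real grouping gave the most genes of the 35 splits of its libraries (1 of 35 as large, the least possible). Chance is unlikely but not excluded. The counts, from fits to those libraries alone, were closest for PSN1 KI-CDK9d-32 against vehicle at 2 h (150 genes, highest other 44). At 4 h in MOLT4 they were 3891 and 297 for KI-CDK9d-32 and 4150 and 378 for KB-0742, where vehicle has 3 libraries. In the other 19 comparisons the highest other split gave at most 35 genes.

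The mean shares of mitochondrial and ribosomal protein mRNAs were higher with both compounds in the 15 comparisons with vehicle, though not always beyond the spread of the libraries, as for mitochondrial mRNAs with KI-CDK9d-32 at 4 h in RH4 (22.5% ± 1.11 against 21.9% ± 1.27). Low RNA input or library yield would raise these shares in libraries with a high spike-in share within a group too, and the within-group slope predicted under 25% of the difference of both families in 11 of the 15, short of the 12 set in advance. As the whole cause it is argued against in MOLT4 and RH4, where even the upper 95% bound of that slope predicted under 50% of the difference of at least 1 family in 6 of 6 and 4 of 4 comparisons, and it stays open in PSN1 (3 of 5). A fall of most other mRNAs per spike-in stays open too, since with spike-in scaling the median mitochondrial mRNA did not rise in 14 of the 15 comparisons (-0.68 to 0.06), but low input lowers every gene under that scaling and predicts the same. That scaling therefore cannot tell these 2 apart in any line. By the within-group slope, low input as the whole cause stays open in PSN1 alone. A slower decay of these mRNAs was not tested.

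Gene length was examined, because a block of elongation might spare short genes. The fifth of genes with the largest span, less the fifth with the smallest, was higher with KI-CDK9d-32 than with KB-0742 at an exact two-sided permutation p of 0.0286, the smallest possible, in 3 of 7 comparisons. These were the 3 of MOLT4 (differences of 0.22, 0.32 and 0.33 in mean log2 CPM at 2, 4 and 8 h, 4 libraries against 4 each, adjusted p = 0.105), and in PSN1 at 8 h the sign was opposite (-0.16, exact p = 0.0286). Gene span is therefore not settled as an explanation, and the length of the spliced transcript is not either, since its difference within span classes was under 25% of that by span, or opposite, in 5 of 7.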
